A study of Homo sapiens with 2 samples.

How the data were processed

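WS1 skin fibroblasts were profiled by total RNA sequencing in 2 libraries, 1 from cells that received 0 Gy and 1 from cells harvested 24 h after 5 Gy of X-rays, per the labels. RNA was extracted with Trizol and libraries were made with the TruSeq Stranded Total RNA kit, per the labels' protocols. Reads were mapped to hg19 with HISAT2 and FPKM compared with Cuffdiff, per the series' design text. CASAVA 1.8 is named in the submitters' processing notes. The versions of HISAT2 and Cuffdiff, the annotation, the filters and the strand setting used in counting are not given in the sources used here.

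The deposited files are an mRNA table per gene and a lncRNA table per transcript, each with an FPKM and a count per library. The FPKM values were deposited as the authors computed them, per the file headers, and how the libraries were scaled to each other is not stated there. The deposited count columns hold estimated counts that need not be whole. From the values, they are fragments multiplied by 1 factor per library, 0.974 for 0 Gy and 1.03 for 5 Gy: of mRNA values up to 20 fragments, 85.8% and 86.5% came out whole within 0.02 after division by that factor. Of the lncRNA values 58.1% and 59.3% did, so lncRNA fragments rest on that factor less firmly. Fragments below are the estimated counts divided by it. Totals were 9815784 and 9536965 fragments in the mRNA table and 1355233 and 1475264 in the lncRNA table, for 0 Gy and 5 Gy. RN7SL1 and RN7SK, both short noncoding RNAs, took 37.2% and 26.7% of the lncRNA fragments at 0 Gy. FPKM of transcripts much shorter than a sequenced fragment is inflated, so that 1 fragment can give a high FPKM. How overlapping and near-identical genes were split is the authors' step, so values of overlapping, antisense or multicopy genes are uncertain.

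The lncRNA table repeats a transcript once for each neighbouring gene: its 86681 rows held 37471 transcripts, whose values were summed to 23602 symbols. The mRNA table, with 20256 genes, was used per gene ID. XIST, TSIX and genes on the Y chromosome were left out. Gene positions and transcript lengths came from GENCODE 44 lifted to GRCh37, the same assembly as hg19. Of the 20256 gene IDs 19575 (96.6%) were found there, all of them overlapping the position in the file. For 459 other IDs the length was taken from the coding gene that shared at least 50% of the joint span.

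The effect size was log2((FPKM at 5 Gy + 1)/(FPKM at 0 Gy + 1)), without rescaling, for genes with a mean FPKM of at least 1; adding 1 understates the difference of low genes. With 1 library per group there is no estimate of spread, so no count model was fitted and no p-value computed. A gene was called where it differed at least 2-fold. Count ratios carry an exact 95% interval (Clopper-Pearson on the share of fragments from 5 Gy), which covers counting error only and not variation between cultures. Where a gene had 0 fragments at 0 Gy, the ratio was taken against a floor of 3 fragments, and the counting interval gives its lower limit. The analysis plan had assumed FPKM alone; the estimated counts were used for these intervals and as an alternative.

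Lists of genes, 27 of mRNA and 1 of lncRNA, were fixed before the data were examined. The median of each list's measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and a list stood apart under percentile 2.5 or over 97.5. This describes these libraries and is not a test of irradiation. Correlations of lncRNAs with neighbouring mRNA genes used the pairs in the authors' table and 10000 random re-pairings. The authors' own differential calls, which the plan had listed, were not analysed here, since the tables used hold no fold or p columns.

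Genes were named by a rule set before the data were examined: CDKN1A, MDM2, GDF15 and FDXR, with 1 more gene; the 12 mRNA genes with the largest increase and the 12 with the largest decrease, clone names left out; up to 4 members of each list with the largest absolute log2 ratio; and the 8 largest increases and decreases of lncRNA plus the measured members of the lncRNA list. Any other gene was chosen after its value was seen. Some genes that the rule names are not reported here.

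Alternatives set beforehand were pseudocounts of 0.1 and 0.5, no expression minimum or a mean FPKM of 5, median centring, upper quartile rescaling, rescaling to a total of 1000000 (TPM), the top transcript for each lncRNA, removal of a running median over expression or over transcript length (501 genes or 101 lncRNAs wide), thresholds of 1.5-fold and 4-fold, and unmatched random lists. Alternatives added after the data were seen were estimated counts in place of FPKM, at least 20 fragments, summed rows of a shared symbol, a counting interval that excludes 1, and random lists matched on length too.

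The steps were tested on simulated data. Fragments were drawn for the 11457 measured mRNA genes, 50 of them at each of 4 known folds. The changed genes were taken from those with a mean of at least 10 fragments. The draws held counting error only, with no variation between cultures and no splitting of shared reads. The rates that follow are therefore not error rates for a comparison with 1 library per group. At least 2-fold was called for 84% of genes with a true 2.5-fold difference, 92% at 3-fold, 98% at 4-fold and 0% at 1.5-fold, and for 0.0444% of 11257 unchanged genes. Of 200 lists drawn at random from all simulated genes, changed ones included, 5.5% fell outside the middle range. They were set against random lists of the same genes, so this rate checks the calculation only. Of the counting intervals 95.8% held the true ratio. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.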

Results

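The study sequenced long noncoding RNA and messenger RNA of WS1, an established line of human skin fibroblasts, without irradiation and 24 h after 5 Gy of X-rays in 1 exposure. Each condition had 1 library, so no difference below has a replicate check, no p-value is given, and every interval covers counting error only. The mRNA table held 9815784 estimated fragments for the 0 Gy library and 9536965 for the 5 Gy library, over 20256 genes. The lncRNA table held 1355233 and 1475264 fragments over 37471 transcripts. After the expression minimum, 11457 mRNA genes and 1205 lncRNA symbols were measured. Log2 ratios are of FPKM (fragments scaled by transcript length and library size) with 1 added, 5 Gy over 0 Gy. Folds with an interval are ratios of the estimated counts with an exact 95% counting interval.

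The first question was how the mRNA of these fibroblasts differed 24 h after irradiation, beginning with genes known to respond to DNA damage. CDKN1A, which encodes the cell cycle inhibitor p21, was at 28.8 FPKM at 0 Gy and 75.4 FPKM at 5 Gy, a 2.72-fold higher count (2.49 to 2.99). MDM2, a ubiquitin ligase, was at 58.2 and 189 FPKM, 2.84-fold higher by count (2.71 to 2.98). FDXR, a mitochondrial reductase used as a radiation marker, was at 18.9 and 71.1 FPKM, and GDF15, a secreted stress cytokine, at 7.86 and 21.3 FPKM. In GRCh37 (hg19) coordinates CDKN1A lies on chromosome 6 at 36644237 to 36655114, MDM2 on chromosome 12 at 69201957 to 69239324, FDXR on chromosome 17 at 72858619 to 72869156 and GDF15 on chromosome 19 at 18485541 to 18499986.

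The list of DNA damage target genes as a whole was higher at 5 Gy. Of its 48 measured genes, 46 lay above 0 on the log2 scale, 22 were at least 1.5-fold higher, 13 at least 2-fold higher and 0 at least 1.5-fold lower. The median log2 ratio was 0.56, above all 10000 random lists matched on expression, whose middle 95% ran from -0.15 to 0.07. TP53I3, a quinone oxidoreductase, was at 40.1 FPKM at 0 Gy and 136 FPKM at 5 Gy (3.72-fold, 3.39 to 4.10). CYFIP2, a regulator of actin, was at 2.34 and 7.75 FPKM (3.90-fold, 3.12 to 4.90). RRM2B, a ribonucleotide reductase subunit on the same list, was close to level at 11.9 and 11.6 FPKM, and BAX, a death effector, stood at 44.4 and 49.5 FPKM; these last genes were singled out after their values were seen.

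**Figure D1:**
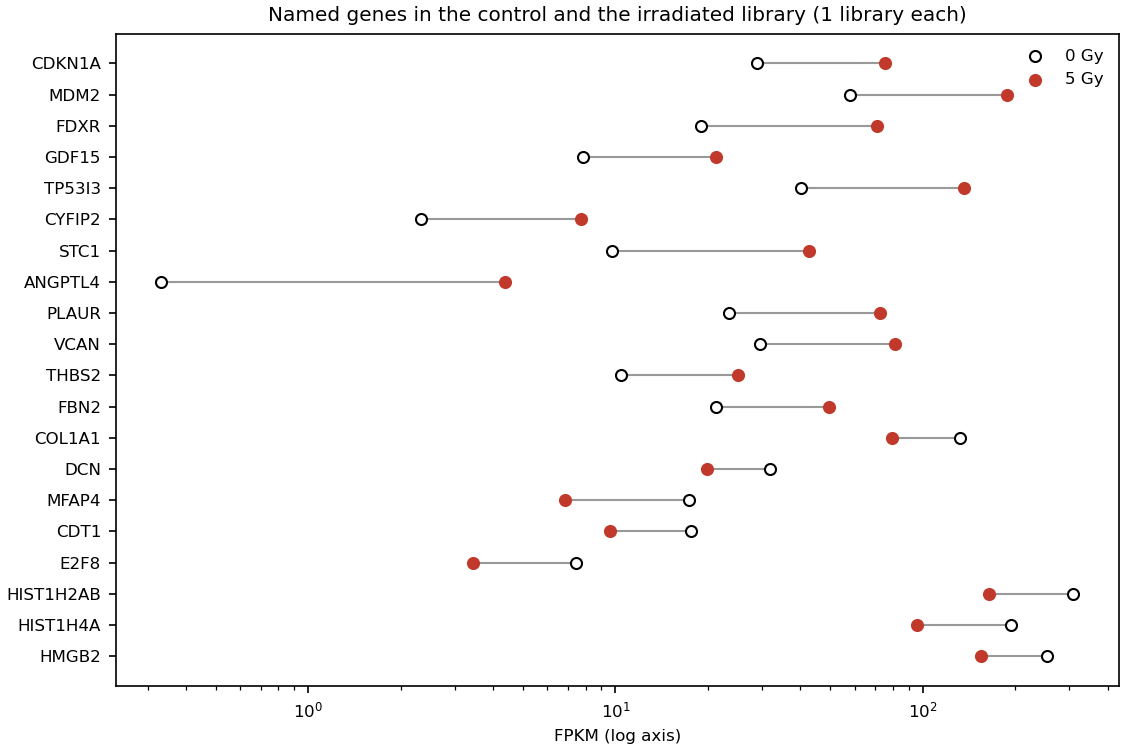
FPKM (log axis) of 20 named genes in the 0 Gy library (open circles) and the 5 Gy library (filled circles), 1 library each, joined by a line. CDKN1A lay at 28.8 FPKM without irradiation and 75.4 FPKM after it, VCAN at 29.6 and 81.5 FPKM, and COL1A1 at 132 and 79.5 FPKM.

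Across all mRNA, 187 of 11457 measured genes (1.63%) were at least 2-fold higher at 5 Gy and 106 (0.925%) at least 2-fold lower, with a median log2 ratio of -0.05. Most ratios were small: 90% of the genes lay between -0.65 and 0.63. The balance depended on the threshold, since 657 genes were at least 1.5-fold higher and 757 at least 1.5-fold lower. A counting interval that excluded 1 was found for 177 of the 187 higher and 99 of the 106 lower genes. The counts were larger with a pseudocount of 0.1 (304 higher and 271 lower) or with rescaling to a common total (343 and 230), which also raised FPKM relative to the pseudocount and let 12350 genes pass. Only 111 and 44 genes passed where the mean FPKM had to reach 5.

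Haemoglobin genes had the largest log2 ratios. HBB, the beta chain gene on chromosome 11 at 5246694 to 5250625, had 0 fragments at 0 Gy and 446 at 5 Gy (85.3 FPKM), a ratio of 157 against a floor of 3 fragments (counting interval from 127 upward). HBA2 and HBA1, near-identical alpha chain genes that share reads, had 0 fragments at 0 Gy and 79.0 and 43.0 at 5 Gy. No other erythroid gene examined reached 10 fragments in either library. ESM1, a secreted proteoglycan on chromosome 5 at 54273695 to 54318499, was 8.91-fold higher by count (7.23 to 11.1). DRAXIN, an axon guidance protein, was at 0.562 and 9.15 FPKM, 16.3-fold higher by count (12.2 to 22.1). COL17A1, a collagen of hemidesmosomes, was at 1.12 and 11.0 FPKM, 9.79-fold by FPKM and 16.5-fold by count (11.3 to 25.2), and CLCA2, a chloride channel regulator, 6.77-fold higher (5.80 to 7.93). The neuronal endosome gene NSG1 had 4 and 78.0 fragments.

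Some of the largest values rested on few or shared reads. SBP1 had 0 and 4.40 fragments. MRPL30 was listed under 2 gene IDs, with log2 ratios of 2.60 and 0.18. HIST2H4A and HIST2H4B, near-identical histone genes, lay apart at 2.19 and -1.03.

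Among the largest decreases, MGP, the matrix Gla protein that restrains calcification, was at 20.7 FPKM at 0 Gy and 5.20 FPKM at 5 Gy (0.254-fold, 0.179 to 0.353). CRABP2, a retinoic acid binding protein, was at 40.5 and 11.5 FPKM (0.306-fold, 0.245 to 0.379). The chemokine CXCL12 was at 37.2 and 12.1 FPKM (0.315-fold, 0.273 to 0.362), and CDKN2C, an inhibitor of cyclin-dependent kinases, at 27.0 and 8.84 FPKM (0.323-fold, 0.272 to 0.382). SEMA6D, a semaphorin, was at 5.25 and 0.902 FPKM, and LGI1, a secreted leucine-rich protein, at 3.31 and 0.526 FPKM. C1orf54 and SCUBE2 had 22.4 and 18.0 fragments at 0 Gy and 2 each at 5 Gy. C1orf213 had 10.0 and 6.59 fragments, with an interval of 0.238 to 2.15 that includes 1. GTF2IRD2 has a near-identical copy, so its value of 0.239-fold is uncertain. UQCR11 was lowest by 1 of its 2 gene IDs only (-2.45); the other, with far more fragments, was at -0.20. MT-ND4L, at -1.55, overlaps its neighbour on the mitochondrial chromosome.

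**Figure D2:**
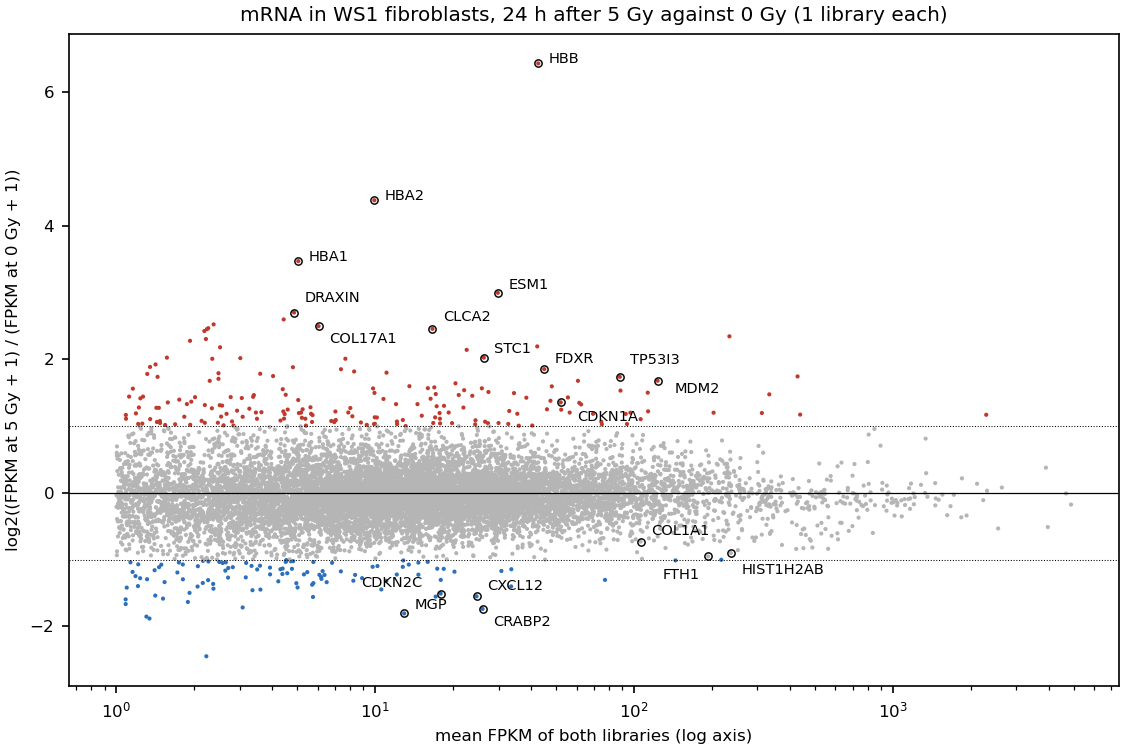
Log2 ratio of FPKM, 5 Gy over 0 Gy, against the mean FPKM of both libraries (log axis) for 11457 mRNA genes. Dotted lines mark 2-fold; 187 genes lay at or above the upper line (red) and 106 at or below the lower one (blue), with HBB at 6.43 the highest.

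Genes of secreted inflammatory and senescence factors were higher at 5 Gy. Of 26 measured, 11 were at least 2-fold higher and 0 at least 1.5-fold lower, with a median log2 ratio of 0.58, above all random lists (1.03 where the mean FPKM had to reach 5). Among them STC1 (stanniocalcin) was at 9.76 and 42.8 FPKM (4.52-fold, 4.07 to 5.03), PLAUR, the urokinase receptor, at 23.4 and 72.8 FPKM (3.20-fold, 2.83 to 3.64), and ANGPTL4, a lipase inhibitor, at 0.332 and 4.36 FPKM (12.9-fold, 6.02 to 33.2). IL6, singled out after its value was seen, had a fold of 1.58 with an interval of 0.721 to 3.60, so no difference was detectable at this depth. Genes of NF-kB feedback did not stand apart (median 0.02, percentile 77.6 of 16 genes), although IER3 was at 42.0 and 74.5 FPKM and RELB at 3.08 and 5.44 FPKM. Interferon response genes did not either (median -0.09, percentile 37.9 of 30 genes); the growth regulator SAMD9L was the 1 gene at least 2-fold lower, at 14.3 and 6.14 FPKM.

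Collagen and matrix genes differed in both directions. The median of 33 genes was 0.17, above the random range, yet 9 genes were at least 1.5-fold higher and 6 at least 1.5-fold lower. The proteoglycan VCAN was at 29.6 and 81.5 FPKM (2.93-fold, 2.80 to 3.06), THBS2 at 10.4 and 25.1 FPKM and FBN2, a fibrillin, at 21.2 and 49.6 FPKM. MFAP4, an elastic fibre protein, was at 17.4 and 6.87 FPKM (0.373-fold, 0.302 to 0.457). The main fibrillar collagen gene COL1A1 was at 132 and 79.5 FPKM (0.668-fold, 0.640 to 0.697), and COL3A1, singled out after its value was seen, at 143 and 71.7 FPKM. TGF-beta and myofibroblast genes had a median of 0.13 (percentile 98.3 of 20 genes), with LTBP2, SMAD7 and CTGF at 1.28, 1.25 and 1.04. That list lay inside the random range after rescaling to a common total and when random lists were also matched on transcript length.

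Stress and early response genes were higher in several lists. Of 16 immediate early genes, 7 were at least 1.5-fold higher and 1 lower, with a median of 0.44, above all random lists (0.76 where the mean FPKM had to reach 5). The phosphatase genes DUSP6 and DUSP1 were at 1.60 and 1.49, the AP-1 member FOSL1 at 1.07 and MYC at 1.03. Unfolded protein and integrated stress response genes had a median of 0.20 (percentile 99.9 of 24 genes), led by ASNS, asparagine synthetase, at 8.57 and 25.7 FPKM (3.22-fold, 2.72 to 3.83), and by PSAT1, SESN2 and CEBPB. Glycolysis and hypoxia genes had a median of 0.14 (percentile 99.5 of 29 genes), with VEGFA at 0.87 and CA12 at 0.86. NRF2 antioxidant genes did not stand apart (median -0.11, percentile 24.5 of 18 genes). Within that list the ferritin genes FTH1 and FTL were lower, at -0.95 and -0.82, and the cystine transporter gene SLC7A11 was higher, at 0.93.

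Genes of DNA replication and chromatin were lower at 5 Gy. Of 44 measured G1/S and DNA replication genes, 39 lay below 0, 6 were at least 1.5-fold lower and 0 higher, with a median of -0.25, below all random lists. E2F8, a cell cycle repressor, was at 7.42 and 3.43 FPKM (0.523-fold, 0.420 to 0.648), and CDT1, a replication licensing factor, at 17.6 and 9.59 FPKM (0.677-fold, 0.588 to 0.777). E2F2, an activator of S phase genes, was at -0.67. Replication-dependent histone genes were lower still: 57 of 59 lay below 0 and 36 were at least 1.5-fold lower, with a median of -0.62, below all random lists. Outside this list, the histone genes HIST2H4A, HIST2H3C and HIST2H2AA3 were at least 2-fold higher, while HIST2H4B was at -1.03. HIST1H2AB was at 309 and 165 FPKM (0.532-fold, 0.480 to 0.589) and HIST1H4A at 194 and 95.7 FPKM (0.490-fold, 0.414 to 0.578); single members share reads with near-identical copies. The lamin, HMG protein and chromatin list had a median of -0.32 (percentile 0.04 of 18 genes), with HMGB2 at 253 and 155 FPKM, EZH2 at -0.56 and HMGA2, which was higher, at 0.67.

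The fixed mitosis and repair lists lay inside the random range, while larger groups from the mRNA table, examined after the results were seen, lay below theirs. Of 48 G2/M and mitosis genes, 38 lay below 0 and 0 passed 1.5-fold in either direction; the median of -0.13 was at percentile 2.76. FOXM1, a mitotic transcription factor, was at 29.3 and 19.3 FPKM and MYBL2 at 29.0 and 20.5 FPKM. Homologous recombination and Fanconi genes had a median of -0.20 (percentile 3.06 of 25 genes), with BRCA1 at -0.55 and RAD54L at -0.48. Both lists lay below the random range under some of the other settings. The G2/M transition group had a median of -0.18 (percentile 0.05 of 96 genes), mitotic nuclear division -0.10 (0.9 of 198), break repair via homologous recombination -0.15 (0.2 of 104) and the Fanconi anemia pathway -0.20 (0.2 of 48). End joining and break signalling genes did not stand apart (median -0.11, percentile 19.5 of 22 genes); H2AFX, the damage histone, was at -0.59 and CHEK1 at -0.43.

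Among housekeeping lists, none stood apart. Reference genes had a median of -0.07 (percentile 38.5 of 16 genes), with ACTB at -0.34 and TFRC at 0.48. Cytosolic ribosomal protein genes (-0.13, percentile 3.07 of 39), oxidative phosphorylation genes (-0.14, percentile 3.72 of 33), cholesterol synthesis genes (-0.13, percentile 9.56 of 23) and autophagy and lysosome genes (0.03, percentile 84.8 of 28) lay inside the random range. RPS2 was at -0.45, NDUFA4 at -0.41, INSIG1 at -0.69 and the lysosomal protease gene CTSL at 0.62. With estimated counts in place of FPKM, or with the expression trend removed, the oxidative phosphorylation list lay below the range. The larger oxidative phosphorylation pathway of the mRNA table, examined after the results were seen, had a median of -0.18 over 104 genes, below all random lists. Those random lists were not matched on transcript length. The macroautophagy group, examined in the same way, had a median of -0.17 (percentile 0.55 of 53 genes).

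Fibroblast identity markers were lower on balance (median -0.26, percentile 0.53 of 20 genes). PDGFRB, a growth factor receptor, was at 31.9 and 16.1 FPKM and the proteoglycan DCN at 31.9 and 19.9 FPKM, while NT5E, the ecto-nucleotidase CD73, was at 58.3 and 135 FPKM. Few markers of other cell types were measured. Of 20 keratinocyte markers, 7 passed the minimum and had a median of 0.65, above the random range of -0.42 to 0.31 (0.128 with no expression minimum, still above its range), with COL17A1, DSG3 (1.03) and PERP (0.69) higher and the basal keratin KRT5 lower (-0.92). Of 14 endothelial markers, 4 passed. TIE1 had 2 and 18.0 fragments and CDH5 32 and 85.0. The better counted TEK (1.00-fold, 0.865 to 1.17) and EGFL7 (1.14-fold, 0.934 to 1.40) showed no difference beyond counting error. The endothelial list, with a median of 0.54, no longer stood apart where the mean FPKM had to reach 5. Immune (2 genes, CD68 at 0.65 and CD14 at 0.10), adipocyte (3 genes, median 0.05) and melanocyte and Schwann cell markers (5 genes, median -0.37) lay inside the random range.

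**Figure D3:**
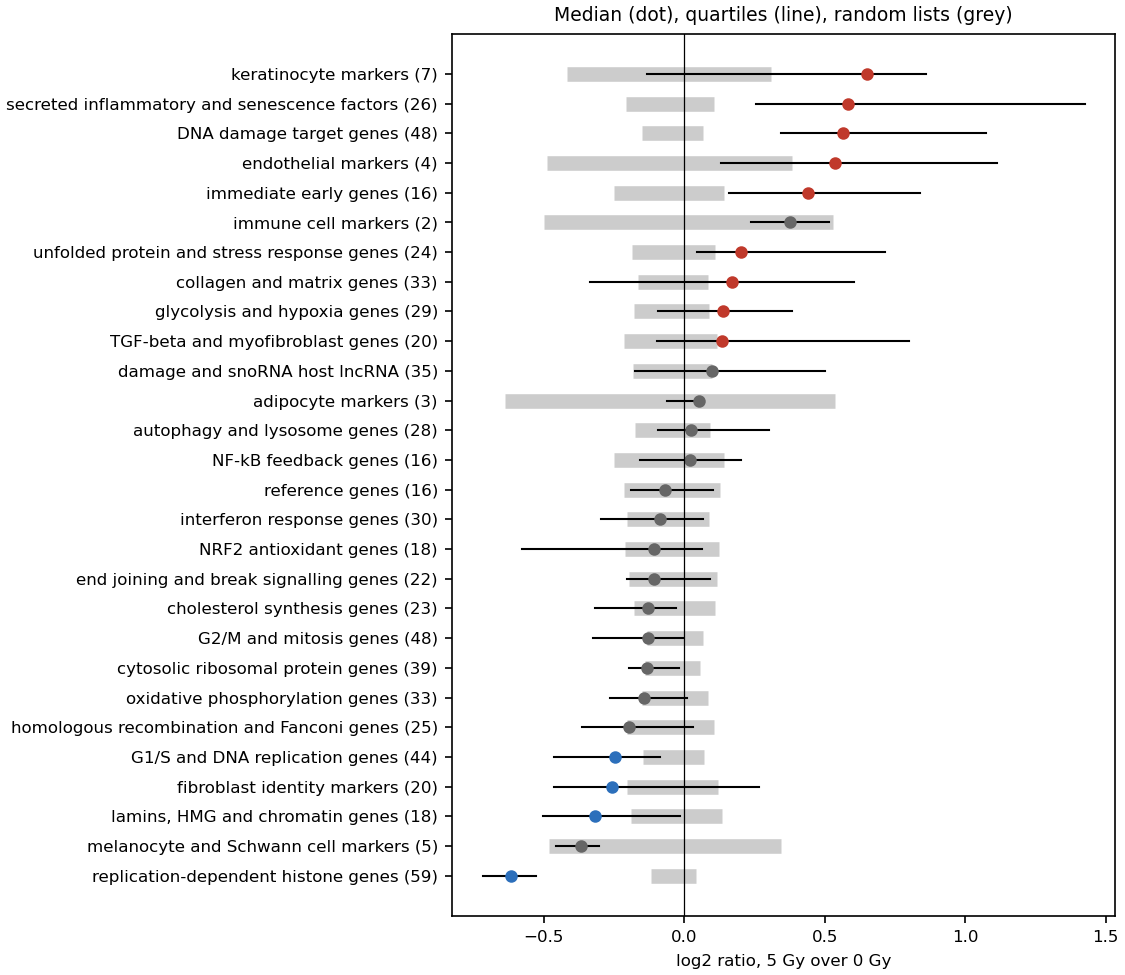
Median log2 ratio, 5 Gy over 0 Gy, of each gene list (dot), the quartiles of its members (line) and the middle 95% of random lists matched on expression (grey bar), with the number of measured genes in parentheses. Red and blue dots lie above and below the random range; DNA damage target genes were at 0.56 and replication-dependent histone genes at -0.62.

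The next question was which long noncoding RNAs differed after irradiation. Of 1205 measured symbols, 63 were at least 2-fold higher at 5 Gy and 77 at least 2-fold lower, so that 45.0% of the called symbols were higher. The median log2 ratio of all symbols was -0.12, and centring on it gave 81 higher and 61 lower (57.0% higher). Of the 140 called symbols, 63 rested on fewer than 10 fragments over both libraries. A counting interval that excluded 1 remained for 34 of the higher and 41 of the lower ones.

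Many of the largest lncRNA ratios were those of short or repeated RNAs. RN7SL2 and RN7SL3, copies of the RNA of the signal recognition particle, were listed at 0 at 0 Gy and at 262112 and 16264 FPKM at 5 Gy. RN7SL1, their near-identical copy, had 503620 fragments at 0 Gy and 396480 at 5 Gy, and the 3 summed had a count ratio of 1.61. An exact 0 beside such a copy can be a failed split of shared reads. SNORD91B (0 and 1 fragments), VTRNA1-3 (2 and 0), RNY3P1 (2 and 0), RNY4P2 (1 and 0) and RMRPP4 (1 and 0) rested on few fragments. MIR663A had 3 fragments at 0 Gy and 1 at 5 Gy, yet 0.606 and 329 FPKM. RN7SL587P had 7 and 0 fragments, and NPCEDRG 14.4 and less than 1. MID1 noncoding transcripts were at -2.39 by FPKM and 0.38 by count, on 3 and 4 fragments. SNHG14 was at 5.82 by FPKM and -0.34 by count (0.788-fold, 0.651 to 0.949), so its direction depended on the unit. MTND5 and cytochrome b are mitochondrial transcripts that overlap MT-ND5 and MT-CYB, whose mRNAs were 1.94-fold and 1.63-fold higher. They had less than 1 and 882 fragments and 146 and 2815, and reads shared with those mRNAs cannot be excluded. C7orf10 noncoding transcripts were 7.35-fold higher (3.40 to 15.9).

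**Figure D4:**
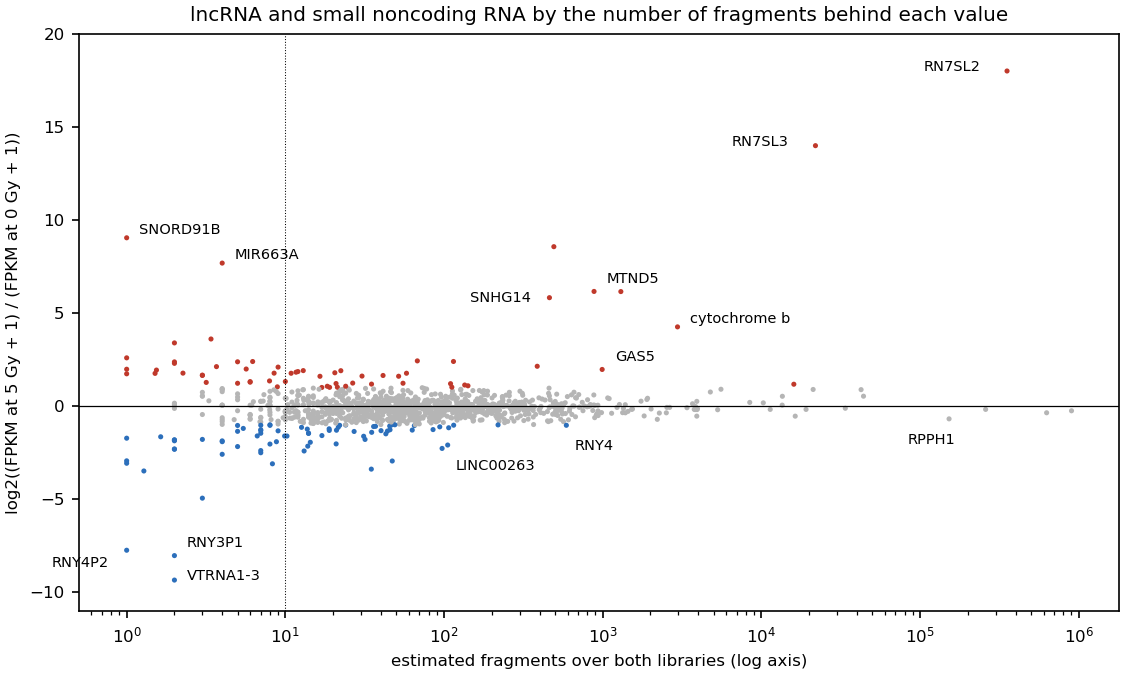
Log2 ratio of FPKM, 5 Gy over 0 Gy, against the estimated fragments over both libraries (log axis) for 1205 lncRNA symbols, with 63 at least 2-fold higher (red) and 77 at least 2-fold lower (blue). The dotted line marks 10 fragments, and SNORD91B and VTRNA1-3, with 1 and 2 fragments, lie left of it.

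Of lncRNAs with at least 100 fragments, MIAT and NEFL were singled out after their values were seen. LINC00263, also among the largest decreases, was at 5.96 and 0.635 FPKM (0.210-fold, 0.122 to 0.361), and MIAT at 3.05 and 1.04 FPKM (0.293-fold, 0.226 to 0.378). MIR17HG, the host of a microRNA cluster, was 3.09-fold higher (1.99 to 4.92), and noncoding transcripts of NEFL 4.42-fold higher (2.86 to 7.06).

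The list of damage and snoRNA host lncRNAs had a median of 0.10 over 35 measured members, just inside the random range of -0.18 to 0.10. It lay above its range under 5 other settings. Median centring, which shifts every symbol alike and so could not change the list's place, gave 0.22. The median turned to -0.0658 with the top transcript of each symbol and to -0.0157 with the length trend removed. Of the 35 members, 7 were at least 1.5-fold higher and 3 at least 1.5-fold lower by FPKM. By count ratio these numbers were 4 and 4, and SNHG14, GAS5, LINC00467 and SNHG8 no longer passed. The snoRNA hosts SNHG12 (1.71-fold by count, 1.41 to 2.08), SNHG15 (1.44-fold, 1.23 to 1.68) and SNHG3 (1.37-fold, 1.33 to 1.42) were higher. So were SNHG8 (1.35-fold, 1.18 to 1.55), EPB41L4A-AS1 (1.31-fold, 1.02 to 1.69), SNHG1 (1.23-fold, 1.13 to 1.35) and SNHG16 (1.19-fold, 1.11 to 1.26). SNHG5 (0.968-fold, 0.849 to 1.10), SNHG6 (1.05-fold, 0.838 to 1.31), SNHG7 (0.924-fold, 0.856 to 0.999), DANCR (0.917-fold, 0.760 to 1.11) and ZFAS1 (1.07-fold, 0.934 to 1.22) were level or lower, and SNHG14 was lower (0.788-fold, 0.651 to 0.949). GAS5 was at 1.97 by FPKM but 1.27-fold by count (1.12 to 1.45). PVT1 was at 0.20. NEAT1 was at -0.14 by FPKM but 1.12-fold by count (1.05 to 1.19), so its direction depended on the unit. MALAT1 was at 1.96 and 0.212 FPKM on 41.7 and 21.3 fragments (0.539-fold by count, 0.296 to 0.910). CDKN2B-AS1 was at -0.79 (0.242-fold by count, 0.132 to 0.426), and RPPH1, the RNA of RNase P, was at -0.68.

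The last question was whether lncRNAs differed in the same direction as the mRNA genes the authors' table pairs them with. Across 725 pairs of 623 lncRNAs and 675 mRNA genes the log2 ratios had a Spearman correlation of 0.18 and a Pearson r of 0.20, while 10000 random re-pairings gave a Spearman value of -0.07 to 0.07 in their middle 95%. Both log2 ratios of a pair had the same sign in 56.1% of the 725 pairs, from 50.9% of intronic antisense to 63.0% of exon sense-overlapping pairs. No random range was computed for that share. Pairs are not independent replicates, and 7 relations were computed. The Spearman value was highest for lncRNAs that overlap exons in the sense direction (0.40, 165 pairs), whose reads can be shared with the mRNA. Bidirectional pairs had a value of 0.25 (145 pairs) and natural antisense pairs 0.12 (285 pairs), just above the re-paired range. Intronic antisense (0.08, 173 pairs), sense intronic (0.16, 97 pairs) and noncoding transcripts of the same gene (0.16, 74 pairs) lay within it. Without an expression minimum the value over all pairs was 0.07 (5163 pairs), and with a mean FPKM of at least 5 it was 0.39 (167 pairs). Random re-pairings were not run for these settings, and the range above holds for the 725 pairs only.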

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

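Estimated counts, the 20-fragment minimum, summed symbols, the interval criterion and length-matched random lists were chosen after the results were seen; the other alternatives were set before. With 1 library per group, pairing, leaving out a library, a replicate block and regrouping could not be run. The top transcript setting did not apply to mRNA, which is given per gene. Of 390 list medians recomputed, 373 kept their side of the random range, among them those of the DNA damage target, secreted factor, G1/S and histone lists in every setting. The 373 include median centring, which shifts every gene alike and so could not change a list's side. Of 1111 recomputed values of named genes, 1037 stayed within counting error, which genes at or near 0 fragments could not exceed. Rescaling moved the median of all mRNA by less than 0.1; the lncRNA median of -0.12 was set to 0 by centring.

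The 187 higher and 106 lower mRNA genes became 657 and 757 at 1.5-fold, 23 and 1 at 4-fold, 304 and 271 with a pseudocount of 0.1, 111 and 44 at a mean FPKM of 5, and 343 and 230 after TPM rescaling. Lower genes numbered 180 with a pseudocount of 0.5 and 199 by estimated counts. The 63 higher and 77 lower lncRNAs became 144 and 227 at 1.5-fold, 21 and 22 at 4-fold, 106 and 165 with a pseudocount of 0.1, 128 and 159 with no filter, 21 and 16 at a mean FPKM of 5, 34 and 41 with an interval that excludes 1, and 28 and 30 with at least 20 fragments. Lower lncRNAs numbered 47 with the length trend removed, which also left 959 of 1205 symbols, and 141 by estimated counts. TPM rescaling also raised FPKM against the pseudocount, and 12350 mRNA genes passed. Thresholds, filters and the interval change how many can pass; other causes were not tested.

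G2/M genes passed below the random range at -0.13 when matched on length and with no filter, at -0.10 after TPM rescaling and at -0.11 with the expression trend removed. Homologous recombination genes did at -0.20 when matched on length and -0.18 after TPM rescaling, and oxidative phosphorylation genes at -0.13 with the expression trend removed and -0.20 by counts. With the length trend removed, oxidative phosphorylation genes were at -0.0371, inside the random range. The lncRNA list passed above it at 0.10 unmatched, at a mean FPKM of 5 and with 20 fragments, at 0.0567 with no filter and at 0.0753 after TPM rescaling. TGF-beta genes returned inside at 0.13 when matched on length and 0.15 after TPM rescaling, and endothelial markers at 0.0820 with a mean FPKM of 5 and 0.18 with 20 fragments, which leave fewer genes. The cause of the other shifts was not tested. The Spearman correlation of lncRNA and mRNA neighbours was 0.0673 with no filter, a setting for which no random re-pairing was run. Among named genes at least 2-fold different at first, the log2 ratios of MIR663A, SNHG14 and MID1 turned to -0.95, -0.34 and 0.38 by estimated counts. Smaller ratios, such as that of NEAT1, were not screened for a change of sign. Among lists outside the random range at first, medians that kept their side but moved by over 1.5 times were those of keratinocyte markers (0.128 with no filter), secreted factors and immediate early genes (1.03 and 0.76 at a mean FPKM of 5), glycolysis genes (0.0922 with no filter, 0.22 with the expression trend removed), TGF-beta genes (0.22 with the length trend removed, 0.34 by counts) and endothelial markers (0.86 with a pseudocount of 0.1, 0.31 with no filter, 0.82 by counts). Medians inside the range that changed sign were those of the lncRNA list (-0.0658 with the top transcript, -0.0157 with the length trend removed), NF-kB genes (-0.0193 at a mean FPKM of 5), adipocyte markers (-0.0502 after TPM rescaling) and reference genes (0.00152 with the expression trend removed). Depth limits the lncRNA values, since 63 of 140 called rested on fewer than 10 fragments.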

Other observations

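Tests and groups in this part were chosen after the results were seen, except the removal of the length trend from the histone list. Groups of 15 to 300 measured genes came from the pathway and process columns of the mRNA table, 212 pathways and 709 processes, each placed among 2000 random lists. The random lists were matched on mean expression but not on transcript length. Genes that charge tRNA were higher at 5 Gy: 37 of 42 aminoacyl-tRNA biosynthesis genes lay above 0 (median log2 ratio 0.26), among them YARS, TARS and IARS. Amino acid transport genes had a median of 0.44 over 19 genes, led by SLC7A5, a carrier of large amino acids, at 7.71 and 37.4 FPKM (4.69-fold, 4.22 to 5.23). Genes of rRNA processing (61 of 91 above 0, median 0.17) and ribosome biogenesis (47 of 67, median 0.20) were higher too, with the helicase DDX21 at 1.03 and the nucleolar protein gene WDR3 at 1.04. ECM-receptor interaction genes had a median of 0.44, with the integrin genes ITGA2 at 1.57 and ITGB5 at 1.20 higher and ITGB4 at -1.09 lower. Each of these groups lay above all of its random lists, but standing apart was common: 39 pathways and 83 processes lay above the middle 95% and 13 and 42 below it.

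Nuclear genes of respiratory complex I were lower: 6 of 37 lay above 0, with a median of -0.26, below all random lists. NDUFC1 was at -0.53 and NDUFB4 at -0.46. A trend with transcript length was not tested for this group. The fixed oxidative phosphorylation list, which includes complex I genes, moved from -0.144 to -0.0371 with the length trend removed, inside the random range. Mitochondrial mRNA, encoded in the organelle, was higher when summed (1.40-fold, 1.39 to 1.41). MT-ATP6, an ATP synthase subunit, was at 1.48 and MT-ND4 and MT-ND1, of complex I, at 1.20 and 1.17, whereas MT-CO1 was at 0.08 and MT-CO2 at -0.57. Nucleotide excision repair genes had a median of -0.15 (percentile 0.15 of 92 genes), though XPC, a damage sensor, was at 0.57. Among small RNAs, RNY1, a Y RNA, was 0.460-fold (0.382 to 0.552), RN7SK, which holds back transcription elongation, 0.773-fold (0.769 to 0.777), and RNY4 0.385-fold (0.319 to 0.464). SNORD3A, the U3 RNA of rRNA processing, was 1.38-fold higher (1.35 to 1.40). These intervals cover counting error only. A further 808 transcripts were listed under the symbol Y_RNA, and how reads were split among such short RNAs is not given in the sources used here.

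Haemoglobin transcripts had 0 fragments at 0 Gy and 569 at 5 Gy summed over the chains, a ratio of 199.9 against a floor of 3 fragments (counting interval from 162 upward), so fragments moved between near-identical haemoglobin genes do not account for them. An erythroid gene programme switched on in the fibroblasts cannot be told apart from blood RNA or another library's reads in the 5 Gy library. For the first, 0 erythroid genes other than haemoglobin reached 10 fragments at 5 Gy, and ALAS2, a haem synthesis gene, had 4. For the second, 1 of 14 white cell genes, SRGN, was higher by at least 10 fragments (41.0 at 5 Gy). LAPTM5 had 1 and 8, S100A8 and S100A9 had 0, and PTPRC, CD74 and HLA-DRA had fewer than at 0 Gy. The 14 summed had 29.0 and 63.0 fragments (2.29-fold, 1.45 to 3.69). Nearly all of that rise came from SRGN, so this sum mostly reflects SRGN and decides little. With 1 library per dose both stay open, as does an effect of irradiation.

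Histone transcripts were lower after 5 Gy, with a list median of -0.62. Removing the trend with transcript length between the libraries left -0.464, below all random lists, over the 51 of 59 genes with a known length, which argues against length as the whole cause. Fewer cells in S phase stays open: the G1/S and DNA replication list was at -0.246, but this was known before the test and decides nothing. The recovery of RNA without a poly(A) tail was not tested and stays open.

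COL17A1, CLCA2 and DSG3, genes of epithelial cells, were higher after 5 Gy. The abundant keratinocyte genes summed had a ratio of 1.21 (1.08 to 1.37). PERP alone gave 284 of 519 fragments at 0 Gy and 465 of 597 at 5 Gy, so this sum mostly reflects PERP and decides little. The keratin genes argue against more keratinocytes in the 5 Gy culture. KRT5 was at 73 and 17.0 fragments, KRT10 at 137 and 84.0 and KRT14 at 0 in both libraries. The other keratins examined had fewer than 10 fragments in each library. Reads shared with near-identical copies could not be excluded by the test used, which had no outcome against them. COL17A1, CLCA2 and DSG3 were each listed under 1 gene ID, with 439, 1214 and 164 fragments at 5 Gy, and were higher by FPKM and by count. How reads were split is not given in the sources used here. A response of the fibroblasts to irradiation was not tested apart from these.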
